A study of Mus musculus with 3 samples.

How the data were processed

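Whole cerebral cortex of adult mice carrying the Htr3a-Cre driver NO176 and a Cre-dependent EGFP/Rpl10a reporter was homogenised, and EGFP-tagged polysomes were captured with anti-EGFP antibodies on magnetic beads, per the labels' protocols. RNA bound to the captured ribosomes was sequenced in 3 libraries, which the labels number as replicates 1, 2 and 3 of the same immunopurified group. The deposited files hold whole-number read counts per gene symbol, not normalized, 1 file per library. STAR 2.0.0e, HTSeq and the mouse build mm10 are named in the submitters' processing notes, without the role of each. The gene annotation, the counting mode and the strand setting behind the deposited counts are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

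Each file lists 32532 gene symbols and 5 lines that name no gene. The latter stayed out of library sizes and tests. Of all records, 11.8%, 11.0% and 13.1% in replicates 1, 2 and 3 fell on no annotated feature, 2.49%, 2.83% and 2.68% were ambiguous between genes and 11.2%, 11.3% and 13.1% had no unique alignment. Low-quality and unaligned records were listed at 0. Gene counts summed to 14383545, 13951332 and 14461053. A gene with 0 counts could have had up to 3 counts, which corresponds to 0.209, 0.215 and 0.207 counts scaled to library size (CPM). Shares of a single library carry Wilson 95% intervals, and intervals and floors cover counting error only.

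Exon lengths came from GENCODE M21, an annotation of GRCm38, the assembly that mm10 denotes. Of the symbols, 23161 matched directly, 727 matched by an older name and 8644 had no length. Symbols with a length held 96.9%, 97.0% and 94.6% of the counts. TPM values were computed here from the deposited counts and the summed length of each gene's merged exons, scaled to the same total in each library over genes with a length. Comparisons used log2(TPM + 0.1), so differences of genes near 0 are understated. TPM corrects for length only as far as the annotated exons match the transcripts that were present. Exons of 19 list genes were overlapped over more than 20% of their length by other genes, measured with bedtools 2.31.1. Coordinates are those of the annotation.

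Before the data were examined, 33 gene lists with 481 entries, 441 distinct genes of which 424 could be measured, were fixed from general knowledge of cortical cell types and gene families. They cover general GABAergic, Htr3a class, MGE class, Vip, Lamp5/Ndnf, Sncg/Cck, Pvalb and Sst interneuron markers, excitatory, striatal projection, Cajal-Retzius and immature neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelial, mural, meningeal, ependymal or choroid and blood cells. The remaining lists hold neuropeptides, receptors for serotonin, acetylcholine, GABA and glutamate, sodium and potassium channels, immediate early, sex-linked, mitochondrial and housekeeping genes, and proteins of the large and small ribosomal subunits. For blood, 3 of 7 genes could be measured, and for mitochondrial genes 0 of 13, so 31 lists are described and those 2 are not. Several lists share genes: 9 of 17 Htr3a class genes, 9 of 14 Vip type genes and 5 of 10 MGE class genes stand in another list too, against 0 of 16 excitatory genes. A gene in both lists of a pair was left out of both. A list level is the median TPM of its members per library, set beside 10000 random lists of the same size drawn from genes with a count.

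With 1 group and no unpurified control, no test between groups exists. The difference between the medians of log2(TPM + 0.1) of 2 lists within each library was tested against 0 with limma 3.58.1 for 20 list pairs, and the difference between 2 genes for 37 gene pairs, two-sided. Each family was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In the list family the moderated spread was fully pooled, which gave every pair the same standard error of 0.226. Adjusted p-values of an unmoderated fit are given where they change a call and for some further list pairs. Past the threshold were 19 of 20 list pairs and 33 of 37 gene pairs. Variation between libraries was tested per gene with a chi-square test of the counts against those predicted by library sizes scaled by the trimmed mean of M-values (TMM), for genes with a mean of at least 1 CPM. Dispersions came from edgeR 4.0.16 with an intercept only, and DESeq2 1.42.0 served as an alternative. R 4.3.3, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

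Both tests were tested on simulated data. At a simulated log2 difference of 1, 96.9% of list pairs and 75.6% of gene pairs were called, and 0.35% and 0.22% at a difference of 0. The simulated pairs were independent and had a common SD. Real pairs share lists or genes, and their SDs ran from 0.09 to 0.69 for lists and from 0.03 to 1.83 for genes. These rates therefore need not hold for the real pairs. The chi-square test recovered 74.5% of 200 genes changed 1.5-fold and 92.5% of 200 changed 2-fold, and called 0.079% of unchanged genes.

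Genes are named by a rule fixed before the data were examined. It takes the 4 highest and the 1 lowest member of each described list by mean TPM, every gene of the 37 pairs and the 20 genes with the highest mean TPM. It also takes the 10 genes with the largest dispersion among those past the chi-square threshold with a mean of at least 10 CPM, and Htr3a and Rpl10a in every library. Genes named outside the rule are said to be so. Some genes that the rule takes, and the pairs that hold them, are not reported here, although they stay in the list medians and in the counts and adjustment of the tests. Alternatives fixed in advance were pseudocounts of 1 and 0.01, CPM in place of TPM, the longest transcript as length, a fit without moderation and leaving out each replicate. For lists they also included the mean in place of the median, members of at least 1 TPM and members of no other list. Scaling, count filters and detection limits were varied for the counts of genes. Members of at least 1500 nt and the length of the principal transcript were added after seeing the data.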

Results

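Ribosome-bound RNA of the adult mouse cerebral cortex was profiled in 3 libraries from a cross of the Htr3a-Cre driver NO176 with a Cre-dependent reporter line. In cells of this cross that have expressed Cre, a stop cassette is lost at the Rosa26 locus and the ribosomal protein Rpl10a is made as a fusion with EGFP. Antibodies against EGFP then pull down the tagged ribosomes together with the messenger RNA they carry, an assay known as translating ribosome affinity purification (TRAP). The question put to the data was which genes are present in ribosome-bound RNA of the cortical interneurons this driver marks. The libraries formed 1 group of immunopurified samples, named replicates 1, 2 and 3. Unpurified cortex RNA was not analysed here, so no enrichment over the tissue was computed, and every comparison set genes or gene lists against one another within the same libraries. The labels do not say whether the replicates came from separate animals, and p-values therefore measure only the spread between these samples, which may be technical. Counts given to genes came to 14383545, 13951332 and 14461053 in replicates 1, 2 and 3. A total of 12153 genes reached a length-corrected level of at least 1 TPM in 3 of 3 libraries, 11759 of them protein-coding. At least 100 TPM was reached by 1771 genes. Values after ± are SDs over the 3 libraries (n = 3) throughout.

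Htr3a, the gene whose regulatory sequence drives Cre in this line and which encodes a subunit of the ionotropic serotonin receptor, stood at 655, 582 and 570 TPM in replicates 1, 2 and 3 (602 ± 46.2). The gene lies on chromosome 9 from 48899213 to 48911099 in GRCm38, and its counts were 3759, 3410 and 3426. Rpl10a, the ribosomal protein fused to EGFP in the reporter, stood at 205, 158 and 151 TPM (172 ± 29.5). It lies on chromosome 17 from 28328471 to 28331033, and counts from its own transcript were not separable from counts of the fusion. Rpl10a and Rpl10, another protein of the large ribosomal subunit, differed by a log2 value of 0.11 (SD 0.47), which was less than the spread between libraries (limma, adjusted p = 0.642).

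GABAergic markers were present at high levels, and those of excitatory neurons were lower but far from absent. Gad2 and Gad1, the enzymes that make GABA, stood at 2196 ± 111 and 519 ± 39.1 TPM. Slc17a7, the vesicular glutamate transporter of most cortical excitatory neurons, stood at 196 ± 56.2 TPM, so that Gad2 was 11.5-fold and Gad1 2.71-fold higher. Gad2 was also 4.24-fold above Gad1. Camk2a, a kinase abundant in excitatory neurons, nevertheless reached 2545 ± 302 TPM. Across the 13 general GABAergic markers the median was 126 ± 9.21 TPM, against 70.9 ± 3.02 TPM across the 16 excitatory markers, a 1.78-fold difference in the direction of the GABAergic list in 3 of 3 libraries.

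The GABAergic list also held the vesicular GABA transporter Slc32a1 at 234 ± 53.7 TPM, with the transcription factor Dlx6 lowest at 10.7 ± 1.45 TPM. Of its 13 members, 8 exceeded 100 TPM in 3 of 3 libraries. The excitatory list was led, after Camk2a, by the postsynaptic calmodulin-binding protein Nrgn at 332 ± 76.4 TPM, then Slc17a7 and the deep-layer transcription factor Fezf2 at 92.8 ± 12.7 TPM. Its lowest member was the dorsal telencephalic factor Emx1 at 1.13 ± 0.647 TPM, and 15 of 16 members reached 1 TPM in 3 of 3 libraries. The log2 difference between the lists was 0.83 (SD 0.09; limma, adjusted p = 0.000802). Gad2 exceeded Slc17a7 by a log2 difference of 3.52 (SD 0.42; limma, adjusted p = 0.000188), which was 2.67 with the principal transcript as length, and Gad1 did so by 1.44 (SD 0.47; limma, adjusted p = 0.00402). Dlx1, a homeobox factor of developing interneurons, stood at 124 ± 10.7 TPM against 81.9 ± 1.48 TPM for Neurod6, a factor of pyramidal neurons (log2 difference 0.59; limma, adjusted p = 0.0110). That call was lost without replicate 1 (0.66) or replicate 3 (0.57), and the difference was 1.92 without the length correction. Slc32a1 and Slc17a7 differed by 0.26 (SD 0.17; limma, adjusted p = 0.133), a direction that turned to -0.68 without the correction for length. Exons of other genes overlapped 24.9% of the Slc32a1 exons. Gad2 exceeded Gad1 by 2.08 (SD 0.15; limma, adjusted p = 0.000225), and by 1.03 with the longest transcript as length.

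**Figure D1:**
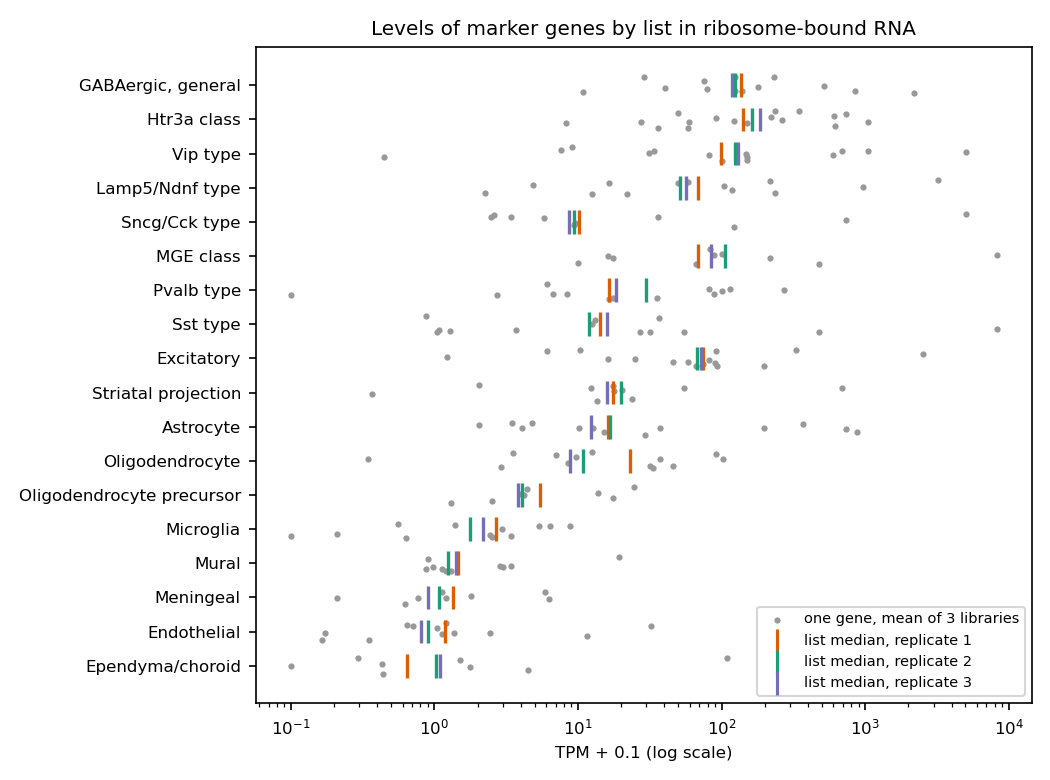
Levels of the genes of 18 marker lists as TPM + 0.1 on a log axis; each grey point is the mean of 1 gene over 3 libraries, and the coloured bars are the list medians in replicates 1, 2 and 3. The general GABAergic, Htr3a class and Vip type medians lie at 126, 163 and 118 TPM on average, and those of the endothelial and ependymal lists near 0.864 and 0.826 TPM.

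Cortical interneurons divide by origin into an Htr3a class from the caudal ganglionic eminence and a class from the medial ganglionic eminence (MGE), which holds the Pvalb and Sst cells. Markers of the Htr3a class were higher as a list than those of the MGE class, at a median of 163 ± 22.1 TPM over 17 genes against 86.1 ± 18.7 TPM over 10 genes. The peptide gene Vip led the Htr3a class list at 1042 ± 169 TPM, ahead of the cannabinoid receptor Cnr1 at 738 ± 171 TPM and the chemokine Cxcl14 at 622 ± 37.5 TPM. The highest MGE class gene, the peptide gene Sst, went against the order of the lists: at 8255 ± 552 TPM it was 7.98-fold above Vip and 13.7-fold above Htr3a. Pvalb, the calcium-binding protein of fast-spiking cells, stood at 88.2 ± 34.5 TPM, and its value of 48.5 TPM in replicate 1 lay below the 106 and 111 TPM of the others.

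The log2 difference between the Htr3a and MGE class lists was 0.94 (SD 0.27; limma, adjusted p = 0.000187), and the Htr3a class also exceeded the excitatory list by 1.20 (SD 0.23; limma, adjusted p = 6.16e-06), both in 3 of 3 libraries. Without moderation these adjusted p-values were 0.0334 and 0.0171 (limma). The class difference was 0.58 without the length correction, 0.62 with the principal transcript as length and 0.52 with list means. It was 1.28 without genes held by several lists. All 17 Htr3a class genes reached 1 TPM in 3 of 3 libraries, the lowest being the transcription factor Sp8 at 8.19 ± 0.971 TPM. The MGE list held, after Sst, the synaptic organiser Elfn1 at 478 ± 76.5 TPM and the potassium channel Kcnc2 at 100.2 ± 4.77 TPM, and the lowest was Nkx2-1, a factor that specifies the MGE, at 9.96 ± 3.67 TPM. Among class-defining regulators, the RNA-binding protein Adarb2 stood at 348 ± 70.3 TPM and the homeobox factor Prox1 at 220.2 ± 43.1 TPM. Both exceeded Lhx6, the homeobox factor of MGE interneurons at 83.1 ± 20.3 TPM, by 4.20-fold (limma, adjusted p = 0.00144) and 2.67-fold (limma, adjusted p = 0.00485). Adarb2 was 21.5-fold above the MGE factor Sox6 (limma, adjusted p = 6.18e-05), Prox1 3.26-fold above Satb1 (limma, adjusted p = 0.000950) and Npas1 2.85-fold above Nkx2-1 (limma, adjusted p = 0.00689, and 0.0591 without moderation). The Prox1 to Satb1 log2 difference of 1.70 fell short of the threshold at 0.18 with the longest or the principal transcript as length. Nr2f2, a nuclear receptor of the caudal eminence at 122 ± 16.6 TPM, was above Lhx6 in 3 of 3 libraries, but the log2 difference of 0.57 (SD 0.45) did not pass the threshold (limma, adjusted p = 0.0654). It did so without replicate 2 (0.81), with the longest transcript as length (1.14) and without the length correction (1.41). Htr3a itself was 7.36-fold above Lhx6 (limma, adjusted p = 0.000262) and 7.26-fold above Pvalb (limma, adjusted p = 0.00156). Without the length correction, the log2 difference of Htr3a minus Lhx6 went from 2.88 to 1.68 and that of Htr3a minus Pvalb from 2.86 to 3.85. Those of Adarb2 and Prox1 minus Lhx6 then went from 2.07 to 3.52 and from 1.41 to 2.22. The log2 difference of Htr3a minus Sst was -3.78 (SD 0.06; limma, adjusted p = 3.23e-05), or -2.25 without the length correction. That of Vip minus Sst was -3.00, or -1.84 with the principal transcript as length and -0.76 without the length correction.

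**Figure D2:**
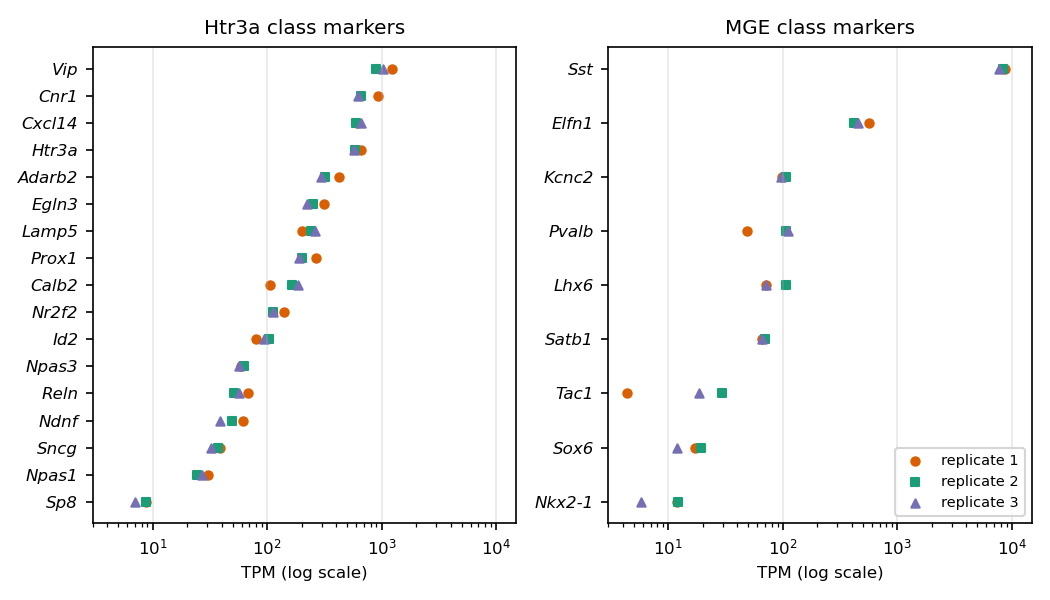
Levels of the Htr3a class (left) and of 9 of the 10 MGE class (right) markers in TPM on a log axis, each symbol being 1 library. The Sst values of the 3 libraries lie between 7653 and 8738 TPM, above every Htr3a class gene, and the Tac1 value of replicate 1 (4.38 TPM) lies below those of replicates 2 and 3.

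Among interneuron types, the Vip type markers had the highest median at 118 ± 17.0 TPM over 14 genes, followed by the Lamp5/Ndnf type at 58.6 ± 8.61 TPM over 13 genes. In each library, the medians of the general GABAergic, Htr3a class and Vip type lists lay above all 10000 random lists of their sizes. The excitatory list lay at percentiles 99.87 to 99.94 of such lists, the MGE class at 99.27 to 99.9 and the Lamp5/Ndnf type at 98.78 to 99.7, and the Vip type was at 98.61 on average with CPM. Medians of the Pvalb, Sst and Sncg/Cck types were 21.5 ± 7.23, 13.9 ± 1.94 and 9.36 ± 0.761 TPM. The Vip list was led by the peptide genes Cck at 5023 ± 1064 TPM, Vip, Penk at 686 ± 110.2 TPM and Tac2 at 596 ± 42.4 TPM, while the nicotinic receptor subunit Chrna2 stood at 0.343 ± 0.287 TPM. Npy, a peptide gene of neurogliaform and many Sst cells, led the Lamp5/Ndnf list at 3220.2 ± 434 TPM, followed by Tnfaip8l3 at 969 ± 222 TPM, the membrane protein Lamp5 at 235 ± 29.9 TPM and the receptor kinase Kit at 219 ± 41.1 TPM. Lsp1 was the lowest Lamp5/Ndnf marker at 2.14 ± 0.792 TPM.

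The Vip list exceeded the Pvalb list 7.54-fold (limma, adjusted p = 1.81e-15), the Sst list 8.47-fold (limma, adjusted p = 3.80e-16) and the Sncg/Cck list 12.4-fold (limma, adjusted p = 2.07e-18). These directions and calls held under the alternatives tried, but the sizes did not. The Vip minus Sst list log2 difference of 3.08 was 1.41 without the length correction, 2.10 with members of at least 1 TPM and 3.95 without genes held by several lists. Vip minus Sncg/Cck went from 3.63 to 2.12 with list means and to 2.21 without genes held by several lists, where Vip minus Pvalb went from 2.92 to 2.30. The Lamp5/Ndnf list exceeded the Sst list 3.87-fold (limma, adjusted p = 1.75e-10), a log2 difference of 1.95 that was 1.26 with members of at least 1 TPM, 3.21 without the length correction and 5.36 without genes held by several lists. It also exceeded the Pvalb list by a log2 difference of 1.49 (SD 0.65; limma, adjusted p = 1.1e-07, and 0.0646 without moderation), which was 3.17 without the length correction and 3.71 without genes held by several lists. The order of the Vip and Lamp5/Ndnf lists was not stable. Their log2 difference of 1.01 (SD 0.41; limma, adjusted p = 7.85e-05, and 0.0596 without moderation) turned to -1.01 without the length correction and to -1.41 without genes held by several lists. Nor was that of the Sst and Pvalb lists, where -0.58 (SD 0.63; limma, adjusted p = 0.0143, and 0.265 without moderation) lost its call without replicate 2 (-0.22) or replicate 3 (-0.76), turned to 0.75 without the length correction and was -1.65 without genes held by several lists. The moderated spread was the same for all 20 list contrasts and many share a list, so their p-values are smaller than independent measurements would give.

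Single members went apart within the Pvalb, Sst and Sncg/Cck lists. The potassium channel Kcnc1 at 270.3 ± 21.6 TPM, the muscle-type cytochrome oxidase subunit Cox6a2 at 115 ± 20.9 TPM, Kcnc2 and Pvalb led the Pvalb list. The secreted peptide gene Ostn had 0 counts in 3 of 3 libraries, which allows up to 0.209, 0.215 and 0.207 library-scaled counts (CPM) in replicates 1, 2 and 3. Sst and Elfn1 led the Sst list, and its next members were the calcium-binding protein Calb1 at 54.7 ± 8.34 TPM and the glutamate receptor subunit Grin3a at 36.4 ± 3.23 TPM. Chodl, a marker of long-range Sst cells, stood at 0.778 ± 0.435 TPM. In the Sncg/Cck list, Cck and Cnr1 were followed by the secretion factor Cadps2 at 122 ± 5.14 TPM and the synuclein Sncg at 36.0 ± 3.47 TPM, with the collagen gene Col14a1 lowest at 2.38 ± 0.222 TPM. Sst was 99.6-fold above Pvalb (limma, adjusted p = 0.000105). Vip was 12.5-fold (limma, adjusted p = 0.00107) and Cnr1 8.76-fold above Pvalb (limma, adjusted p = 0.00229). These log2 differences of 3.64 and 3.13 were 5.34 and 5.75 without the length correction.

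Neuropeptide genes spanned the range from the most abundant transcripts of the libraries to no count. Sst, Cck, Npy and Vip led the 27 genes, 8 of which exceeded 100 TPM in 3 of 3 libraries, and the orexin precursor gene Hcrt had 0 counts in 3 of 3. The list median was 16.3 ± 3.04 TPM. Cck was 4.79-fold above Vip (limma, adjusted p = 0.000225) and Npy 3.10-fold above Vip (limma, adjusted p = 0.00195). The Npy to Vip log2 difference of 1.63 turned to -0.96 without the length correction and lost its call at 0.48 with the principal transcript as length (limma, adjusted p = 0.0819). The Npy exons cover 566 nt and those of Vip 3402 nt. The extracellular matrix gene Reln at 58.6 ± 8.61 TPM lay 17.7-fold below Vip (limma, adjusted p = 2.91e-05), and the secreted factor Ndnf at 50.0 ± 11.4 TPM lay 20.98-fold below it (limma, adjusted p = 5.28e-05). Without the length correction the log2 difference of Reln minus Vip went from -4.15 to -1.35, that of Ndnf minus Vip from -4.39 to -2.82 and that of Cck minus Vip from 2.26 to 0.88. With the principal transcript as length, Ndnf minus Vip was -5.54. Lamp5 lay 4.43-fold below Vip (limma, adjusted p = 0.000758). Sst exceeded Vip in 3 of 3 libraries (limma, adjusted p = 0.000105). The calcium-binding protein Calb2, found in a subset of Vip cells, stood at 151 ± 41.6 TPM. It was 1.78-fold above Pvalb (limma, adjusted p = 0.00689) and 2.71-fold above Calb1 (limma, adjusted p = 0.00229). Without the length correction, Calb2 minus Calb1 turned to a log2 difference of -0.03 and Calb2 minus Pvalb went from 0.83 to 1.57.

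Markers of glial and vascular cells lay below the GABAergic list. The median of the 13 astrocyte markers was 15.03 ± 2.37 TPM, that of the 13 oligodendrocyte markers 14.1 ± 7.62 TPM and that of the 8 oligodendrocyte precursor markers 4.33 ± 0.857 TPM. Microglial, mural, meningeal, endothelial and ependymal or choroid lists had medians of 2.11 ± 0.455, 1.28 ± 0.114, 1.01 ± 0.221, 0.864 ± 0.198 and 0.826 ± 0.245 TPM. Single genes stood high within the astrocyte list. The sodium pump subunit Atp1b2 at 879 ± 222 TPM, glutamine synthetase Glul at 732 ± 46.5 TPM, the glutamate transporter Slc1a2 at 370 ± 43.9 TPM and the aldolase Aldoc at 199 ± 18.4 TPM led it. Its lowest member was the gap junction gene Gja1 at 1.95 ± 0.547 TPM.

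The GABAergic list exceeded the astrocyte list 8.39-fold (limma, adjusted p = 3.81e-16), the oligodendrocyte list 9.70-fold (limma, adjusted p = 5.61e-17) and the precursor list 28.8-fold (limma, adjusted p = 7.94e-23). It exceeded the microglial list 58.3-fold (limma, adjusted p = 8.54e-26), the mural list 93.1-fold (limma, adjusted p = 2.03e-27) and the endothelial list 138-fold (limma, adjusted p = 1.67e-28). It was 7.13-fold above the striatal projection neuron list (limma, adjusted p = 4.04e-15), whose 10 genes had a median of 17.8 ± 2.10 TPM. That list was led by Penk, the phosphodiesterase Pde10a at 54.8 ± 10.6 TPM, the dopamine-regulated phosphatase inhibitor Ppp1r1b at 23.8 ± 1.61 TPM and the dopamine receptor Drd1 at 20.2 ± 5.40 TPM. Its homeobox gene Isl1 was lowest at 0.270 ± 0.391 TPM. Without moderation of the spread, the adjusted p-values of these GABAergic differences lay between 0.00271 and 0.0171 (limma). The tests measured the spread between libraries, not that between the genes of a list. The sizes of these differences depended on the choices made. GABAergic minus microglial markers went from a log2 difference of 5.87 to 7.35 without the length correction, and GABAergic minus oligodendrocyte markers from 3.28 to 4.0. With members of at least 1 TPM, the difference to microglial markers was 5.28, and the differences to endothelial and mural markers went from 7.11 to 6.03 and from 6.54 to 5.88. The difference to astrocyte markers went from 3.07 to 2.22 with list means, and that to striatal projection neuron markers from 2.83 to 3.50 without the length correction. Excitatory markers exceeded those of astrocytes 4.72-fold (limma, adjusted p = 4.38e-12, and 0.00822 without moderation) and of oligodendrocytes 5.46-fold (limma, adjusted p = 3.46e-13, and 0.0334 without moderation). With list means in place of medians, the excitatory to astrocyte log2 difference was 0.84 against 2.24. Astrocyte and oligodendrocyte lists differed by a log2 value of 0.21 (SD 0.61; limma, adjusted p = 0.361), and by 0.56 without replicate 1, which then passed the threshold (limma, adjusted p = 0.0149). In replicate 1, 12 of 13 oligodendrocyte markers were higher than the mean of the others, with a median ratio of 1.52 (log2 0.61), and so were 7 of 8 precursor markers. The same held for 8 of 12 endothelial (log2 0.88), 5 of 8 meningeal (log2 0.48) and 11 of 18 acetylcholine receptor genes (log2 0.51). Of these, 5 endothelial, 3 meningeal and 4 acetylcholine receptor genes lay below 1 TPM in 3 of 3 libraries, so these log2 values are uncertain. Shares in other lists ran both ways, with 10 of 13 Sst type (log2 0.16), 15 of 19 channel (log2 0.20) and 3 of 13 Pvalb type genes (log2 -0.06) higher. Long transcripts were also higher in replicate 1, by a median log2 difference in TMM-scaled CPM of 0.19 in the longest of 5 groups of genes by length. The group with a median exon length of 3809 nt stood at -0.06. Exons of Cnp, the middle oligodendrocyte marker by exon length, cover 3639 nt. The length trend was thus smaller than the oligodendrocyte rise, and the cause of that rise was not tested.

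Myelin genes of the oligodendrocyte list included Cnp at 103 ± 30.2, Mal at 46.0 ± 13.0 and Mbp at 37.3 ± 0.220 TPM, and the membrane protein Opalin was lowest at 0.245 ± 0.247 TPM. Precursor markers were led by Olig1 at 24.3 ± 2.89, C1ql1 at 17.4 ± 5.28, Olig2 at 13.7 ± 4.79 and Gpr17 at 4.29 ± 0.796 TPM, and the proteoglycan Cspg4 was lowest at 1.21 ± 0.929 TPM. The microglial genes P2ry12, C1qb and Ctss stood at 6.25 ± 2.37, 5.27 ± 3.98 and 3.31 ± 0.857 TPM, with 0 counts of the receptor Trem2 in 3 of 3 libraries. Glucose transporter Slc2a1 led the endothelial list at 32.4 ± 8.18 TPM, followed by Itm2a at 11.4 ± 4.75, Esam at 2.35 ± 1.13 and Ly6c1 at 1.28 ± 0.589 TPM, with the growth factor receptor Kdr lowest at 0.0643 ± 0.0797 TPM. Mural genes Rgs5, Tagln, Vtn and Acta2 stood at 19.4 ± 0.319, 3.29 ± 2.55, 2.90 ± 0.837 and 2.76 ± 1.20 TPM, and the receptor Notch3 at 0.780 ± 0.459 TPM. Other genes overlap 67.9% of the Tagln exons. Meningeal genes were led by Dcn at 6.15 ± 1.23, Aldh1a2 at 5.80 ± 3.09, Col1a1 at 1.71 ± 0.519 and Slc6a13 at 1.11 ± 0.773 TPM, and Col3a1 was lowest at 0.110 ± 0.0988 TPM. The phospholipase Enpp2 stood apart from the other ependymal and choroid genes at 108 ± 22.7 TPM. Next were Foxj1 at 4.41 ± 2.20, Ccdc153 at 1.66 ± 1.67 and Kl at 1.41 ± 0.429 TPM, while Folr1 had 0 counts. Gad1 was 52.1-fold above the astrocyte water channel Aqp4 (limma, adjusted p = 2.91e-05) and 178-fold above the microglial receptor Cx3cr1 (limma, adjusted p = 2.67e-05). Gad1 was also 21.7-fold above Ppp1r1b (limma, adjusted p = 2.91e-05). With the principal transcript as length, the log2 differences to Aqp4 and Cx3cr1 went from 5.70 to 6.58 and from 7.48 to 8.64. Without the length correction, that to Ppp1r1b went from 4.44 to 5.82. The endothelial junction gene Cldn5 had 0, 3 and 0 counts, so no fold is given for Gad1 over it.

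Htr3a was the most abundant serotonin receptor gene by TPM, at 602 TPM against 121 TPM for the next, Htr5a, a pair that was not tested. Exons of Htr5a cover 5376 nt and those of Htr3a 2083 nt, so the length correction widened that gap. Htr3a was 41.9-fold above Htr3b, the partner subunit (limma, adjusted p = 5.28e-05), 18.1-fold above Htr2a (limma, adjusted p = 2.91e-05) and 19.3-fold above Htr2c (limma, adjusted p = 2.91e-05). Without the length correction, the log2 difference to Htr2a went from 4.18 to 2.75 and that to Htr2c from 4.27 to 2.11. The 14 serotonin receptor genes had a median of 8.26 ± 1.27 TPM, with Htr5a at 121 ± 28.7, Htr2a at 33.2 ± 2.80, Htr2c at 31.1 ± 2.44 and Htr2b, the lowest, at 0.223 ± 0.385 TPM. Among 18 acetylcholine receptor genes, at a median of 4.75 ± 0.823 TPM, the nicotinic subunit Chrna4 led at 165 ± 37.5 TPM, followed by the muscarinic receptor Chrm1 at 66.1 ± 4.39, Chrna7 at 38.7 ± 9.52 and Chrnb2 at 27.7 ± 1.45 TPM. Chrna4 was 4.26-fold above Chrna7 (limma, adjusted p = 0.000188), a log2 difference of 2.09 that was 1.11 with the principal transcript as length, while Chrna9 and Chrna10 had 0 counts in 3 of 3 libraries.

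GABA receptor genes had a median of 44.6 ± 5.79 TPM over 20 genes and included the subunit Gabrb2 at 372 ± 84.5 TPM and the metabotropic receptor Gabbr2 at 310.1 ± 42.1 TPM. Gabrp was lowest at 0.0351 ± 0.0608 TPM. Glutamate receptor genes had a median of 38.1 ± 3.07 TPM over 25 genes, led by the AMPA receptor subunits Gria3 at 254 ± 26.3, Gria1 at 186 ± 19.4, Gria2 at 167 ± 3.55 and Gria4 at 110.0 ± 14.4 TPM. The lowest was the NMDA receptor subunit Grin3b at 0.424 ± 0.455 TPM. Sodium and potassium channel genes had a median of 116 ± 5.72 TPM over 19 genes, above all 10000 random lists of that size in each library. The highest were Kcna1 at 289 ± 27.1, Scn8a at 287 ± 34.2, Kcnc1 and Kcna2 at 239 ± 36.7 TPM, and the pacemaker channel Hcn2 was lowest at 10.4 ± 0.970 TPM. Activity-regulated immediate early genes had a median of 26.5 ± 8.01 TPM over 11 genes. Egr1 at 553 ± 60.4, Dusp1 at 149 ± 8.60, Arc at 72.7 ± 10.8 and Nr4a1 at 41.0 ± 12.3 TPM led them, and Junb was lowest at 3.93 ± 1.99 TPM. These receptor, channel and activity lists were described without a test.

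The most abundant transcript by mean TPM was that of Vsnl1, a neuronal calcium sensor, at 27452 ± 7336 TPM. Snap25, a protein of the vesicle fusion machinery, stood at 16422 ± 2173 TPM and calmodulin gene Calm2 at 14693 ± 1013 TPM. The adaptor protein Ywhaz at 8905 ± 240 TPM and Sst completed the 5 highest. Also among the 20 highest were the tubulin Tubb4a, the proton pump subunit Atp6v1g2, Clip3, the vesicle protein Vamp2 and Cck, between 6053 and 5023 TPM. Ywhae, the sodium pump subunit Atp1b1, the synaptic vesicle protein Syn1, Ywhab, the ATP synthase subunit Atp5b, the trafficking GTPase Rab6a, the mitochondrial carrier Slc25a4, the glycolytic enzyme Gapdh and Npy stood between 4751 and 3220.2 TPM. The 12 housekeeping genes had a median of 513 ± 49.5 TPM and were led by Ywhaz, Gapdh at 3242 ± 288, the actin gene Actb at 1592 ± 64.2 and the elongation factor Eef1a1 at 1245 ± 94.9 TPM.

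Ribosomal protein genes were lower in replicate 1 than in the other libraries. The 46 genes of the large subunit had medians of 69.5, 142 and 157 TPM in replicates 1, 2 and 3, and the 32 of the small subunit 65.2, 124 and 134 TPM, and 75 of these 78 genes had their lowest value in replicate 1. Rpl4 at 1030.2 ± 170.0, Rpl31 at 711 ± 53.0, Rpl41 at 640.3 ± 277 and Rpl19 at 423 ± 163 TPM led the large subunit, while the small included Rps15 at 622 ± 241, Rps3a1 at 429 ± 186 and Rps23 at 380 ± 70.7 TPM. Rpl26 had 0 counts and Rps19 stood at 16.6 ± 3.41 TPM. Members of this family share sequence with many pseudogenes, so their single levels are uncertain. Short transcripts in general were lower in replicate 1: from the shortest to the longest of 5 groups by principal transcript length, the median log2 difference in CPM between replicate 1 and the mean of the others was -0.31, -0.04, 0.02, 0.10 and 0.19.

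**Figure D3:**
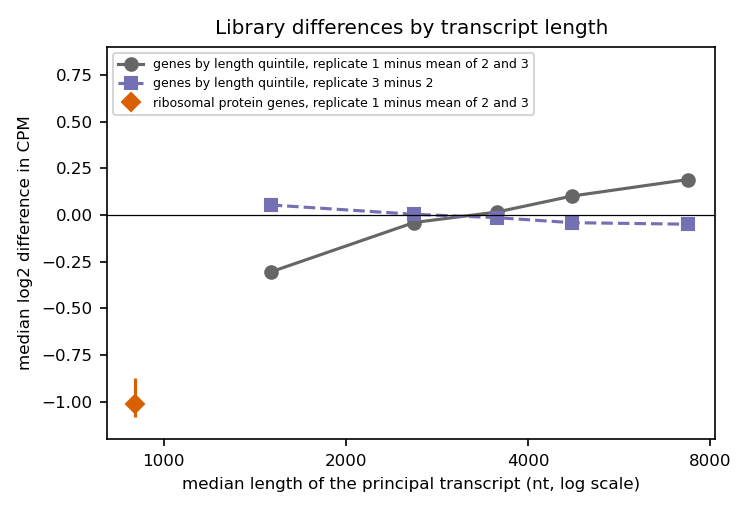
Median log2 difference in CPM against the median length of the principal transcript (nt, log axis) for 5 groups of genes by length; grey circles show replicate 1 minus the mean of replicates 2 and 3, purple squares replicate 3 minus replicate 2, and the orange diamond the 74 ribosomal protein genes with a bootstrap 95% interval over genes. The grey line runs from -0.31 to 0.19 and the diamond, which leaves out Rpl10a, lies at -1.01.

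Beyond these families, 10 genes varied most between the libraries by the rule of largest dispersion. AK220016 and Vwa5a were high in replicate 1, at 42.9 and 40.5 TMM-scaled CPM against 4.98 and 8.13 in replicate 2 and 4.72 and 3.58 in replicate 3. Tac1, the substance P precursor gene, went the other way with 2.99, 19.9 and 12.2 CPM in replicates 1, 2 and 3. Uqcrq and Atp5e, subunits of respiratory chain complexes, stood at 4.08 and 9.04 CPM in replicate 1 against 16.5 and 37.01 in replicate 2. The RNA-processing gene Lsm3, the proline transporter Slc6a7, Mpnd, Tmem158 and Slc35a1 were likewise lowest in replicate 1. Of 12949 genes with a mean of at least 1 CPM, 9620 (74.3%) varied more than counting noise allows by a chi-square test with Benjamini-Hochberg adjustment. Between replicates 2 and 3 alone, 5542 did so. The share of genes that differed was 54.9% between replicates 1 and 2, 62.4% between 1 and 3 and 42.7% between 2 and 3, so no library was a copy of another. The median biological coefficient of variation from edgeR was 0.224, and 0.155 without replicate 1. Across those genes, Pearson's r of log2(CPM + 0.1) was 0.969 between replicates 1 and 2, 0.958 between 1 and 3 and 0.975 between 2 and 3, where genes are not independent replicates.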

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

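The 45S ribosomal RNA precursor gene Rn45s lay outside the TPM comparisons, since it had no annotated length. Its counts stayed in the library sizes, the chi-square test and the correlations between libraries. It drew attention because its signal exceeded by far the limit that a count of 0 allows. It took 2.07% of the gene counts in replicate 1 (Wilson 95% interval 2.07% to 2.08%), 1.97% in replicate 2 (1.96% to 1.97%) and 4.45% in replicate 3 (4.44% to 4.46%). These are 298214, 274394 and 643668 counts, and the intervals cover counting error only. The share was higher in replicate 3 than in the others, while the ribosomal protein genes stood apart in replicate 1. No explanation of the Rn45s share was tested. Groups of 3 libraries are too small for a test of outlying samples.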

How the results depend on the processing

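Chosen after seeing the data were only the alternatives with members of at least 1500 nt and with principal transcript lengths. Of the 20 list contrasts, between 16 and 20 passed the threshold under each alternative, as did 32 to 35 of the 37 gene pairs, against 19 and 33. The fold moved by over 1.5 times for 24 of 37 gene pairs and 9 of 20 list pairs with CPM, for 17 gene pairs and 1 list pair with the principal transcript, for 12 gene pairs with the longest, and for 1 gene pair each with a pseudocount of 1, of 0.01 and without replicate 2. It moved so for 7 of 20 list pairs without genes of several lists, 6 with list means, 6 with members of at least 1 TPM, 4 with members of at least 1500 nt and 2 with a pseudocount of 1. No paired analysis was possible because there is 1 group. The Sst minus Pvalb list difference was -0.56 with a pseudocount of 1, -0.79 with the longest transcript, -0.58 without moderation and -0.14 with list means, none past the threshold. It turned to 0.75 with CPM, 0.082 with members of at least 1 TPM and 0.20 with members of at least 1500 nt, and ranged from -0.77 to -0.22 with a replicate left out. Vip minus Lamp5/Ndnf turned to -1.01 with CPM and -1.41 without genes of several lists, and lost its call at 1.01 without moderation and at 0.32 with members of at least 1500 nt. Lamp5/Ndnf minus Pvalb lost its call at 1.49 without moderation. Astrocyte minus oligodendrocyte passed the threshold at 0.53 with CPM and 1.21 with list means, turned to -0.36 with members of at least 1 TPM, and ranged from 0.0002248 to 0.56 with a replicate left out. Among gene pairs, Slc32a1 minus Slc17a7 turned to -0.68 with CPM, -0.54 with the longest and -0.62 with the principal transcript. With CPM, Npy minus Vip turned to -0.96 and Calb2 minus Calb1 to -0.035. Npy minus Vip also lost its call at 0.48 with the principal transcript. Rpl10a minus Rpl10 turned to -0.44 with the longest transcript and ranged from -0.11 to 0.36 with a replicate left out. Genes varying between libraries numbered 5542 without replicate 1 and up to 8071 otherwise, fewer libraries being compared, and 7938 genes reached 10 TPM. With CPM, 20 of 31 list percentiles moved by more than their SD between libraries. Except for the effect of fewer libraries, the cause was not tested. Genes with few counts, such as Cldn5 with 3, are limited by depth.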

Other observations

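The tests of trends with length and GC content were chosen after the ribosomal protein values had been seen, and that of principal transcript length after the result for exon length. Tests of Rpl10a and of a shared background were set before the data were examined.

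Markers of immature neurons and Cajal-Retzius cells were present at low to moderate levels. The 11 immature neuron genes had a median of 18.0 ± 0.520 TPM (SD, n = 3), led by the tubulin Tubb3 at 129 ± 21.3, the surface protein Cd24a at 54.3 ± 2.81, the interneuron factor Dlx2 at 28.7 ± 2.92 and Sp9 at 21.9 ± 1.02 TPM. Igfbpl1, an immature neuron marker, was lowest at 0.149 ± 0.258 TPM. Dcx, a microtubule protein of migrating neurons, stood at 21.2 ± 2.78 TPM, and the proliferation marker Mki67 at 0.966 ± 0.174 TPM, both named after their values were seen. The 7 Cajal-Retzius genes had a median of 4.06 ± 1.20 TPM, led by Reln, the calcium channel subunit Cacna2d2 at 38.2 ± 1.31, Ebf3 at 7.07 ± 1.08 and Trp73 at 4.06 ± 1.20 TPM. The transcription factor Lhx1 was lowest at 0.593 ± 0.877 TPM.

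Among the excitatory markers, deep-layer transcription factors stood above upper-layer ones by TPM, a set named after its values were seen and not tested. Fezf2, Tbr1, Tle4 and Bcl11b, factors of deep-layer projection neurons, were at 92.8 ± 12.7, 91.6 ± 8.81, 74.7 ± 2.63 and 66.3 ± 4.51 TPM. Rorb, a layer IV factor, was at 46.0 ± 10.7 TPM and Cux2, an upper-layer factor, at 16.02 ± 1.74 TPM. The place of Rorb depended on the length correction. Its exons cover 11076 nt and those of Fezf2 3047 nt, and without the correction Rorb stood above Fezf2. Bcl11b is also made by interneurons.

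Sex-linked genes had a median of 7.41 ± 2.51 TPM over 6 genes. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 45.3 ± 10.9, 11.98 ± 4.51, 9.12 ± 3.48 and 6.22 ± 1.91 TPM, and all 4 had counts in each library. Xist, the RNA of the inactive X chromosome, had 128, 5 and 88 counts in replicates 1, 2 and 3, and its antisense partner Tsix had 0 counts.

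Ribosomal protein genes were lower in replicate 1: 75 of 78 had their lowest value there, against 26 if each library were as likely. Rpl10a was left out of the trend tests, and it was highest in replicate 1, at 205 TPM against 158 and 151 TPM. Over 74 other ribosomal protein genes with at least 10 CPM, the median log2 difference to the mean of replicates 2 and 3 was -1.01 (bootstrap 95% interval over genes -1.08 to -0.87). Genes are not independent replicates, so the intervals given here cover the spread between genes and not that between libraries. A trend with GC content left -0.90 (-0.99 to -0.79) after its removal, which argues against GC content as the whole cause. Removing the trend with exon length left -0.62 (-0.71 to -0.48), with both -0.60 (-0.71 to -0.47) and with principal transcript length -0.46 (-0.53 to -0.34). These lie farther than 0.2 from 0, the distance set for a full account. The bound set for excluding such a trend was a median below -0.5. The medians for exon length and for both lie below it, but their intervals reach above it. The median for principal transcript length does not lie below it. Before any correction, 331 other genes of like principal length were at -0.43 (-0.54 to -0.37) and 984 of like exon length at -0.25 (-0.29 to -0.21), against -1.01 for the ribosomal protein genes. The annotated lengths thus left part of the difference without an account. The bound for excluding a trend with length was met by the median for exon length, but not by its interval or by principal length. The lengths of the transcripts present were not measured. Whether such a trend or a shift particular to these genes made up the rest stays open, and no biological explanation was tested, since the design has 1 group.

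Marker transcripts of excitatory neurons and glia were present in the immunopurified RNA, with Camk2a at 2545 ± 302, Nrgn at 332 ± 76.4, Atp1b2 at 879 ± 222, Glul at 732 ± 46.5 and Cnp at 103 ± 30.2 TPM. These genes stood above their list medians of 70.9 ± 3.02 (excitatory), 15.03 ± 2.37 (astrocyte) and 14.1 ± 7.62 TPM (oligodendrocyte). The lowest excitatory and astrocyte members, Emx1 and Gja1, stood at 1.13 ± 0.647 and 1.95 ± 0.547 TPM. Whether the tagged interneurons make transcripts of these lists themselves was not tested. One candidate explanation is a shared background of whole-cortex RNA, which would hold the differences between the excitatory, astrocyte and oligodendrocyte medians nearly constant between libraries. Their SDs were 0.26 for excitatory minus astrocyte, 0.61 for astrocyte minus oligodendrocyte and, at most, 0.69 for excitatory minus oligodendrocyte. Its chi-square interval of 0.36 to 4.33 lies above the 0.2 set for a shared background but reaches below the 0.5 set for excluding it. That of excitatory minus astrocyte, 0.14 to 1.65, spans both. The prediction also had the lists vary more against the GABAergic list. Those SDs were 0.09 for excitatory, 0.18 for astrocyte and 0.62 for oligodendrocyte markers. It further had the lists share an order over libraries, but the astrocyte median was highest in replicate 2 and the oligodendrocyte median in replicate 1. These parts were not met, though SDs of 3 libraries are uncertain. With 3 libraries, such a background cannot be told apart from tagged ribosomes in those cells or from a background whose makeup differs, and none of the 3 lists shares a gene with another list.

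Reads of the EGFP/Rpl10a fusion could be counted on Rpl10a and raise it among ribosomal protein genes, a hypothesis that needed a percentile above 95 in 3 of 3 libraries and was to be dropped at or below 75 in 3 of 3. Rpl10a stood at percentile 85.7, 61.0 and 53.2 of the other ribosomal protein genes in replicates 1, 2 and 3. Neither bound was met. Rpl10a itself was highest in replicate 1, at 205 TPM against 158 and 151 TPM in replicates 2 and 3. The median of the others was lowest there, at 69.0 TPM against 135 and 143 TPM. The contribution of the fusion stays open.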
